A study of Mus musculus with 12 samples.

How the data were processed

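Kidney RNA of male mice aged 8 to 12 weeks was sequenced in 12 libraries, 3 in each of 4 groups. The groups crossed genotype (wild type, WT, or a conditional knockout of Krt20 in renal proximal tubular cells, cKO) with surgery (sham, or ischemia/reperfusion, IR). In IR the vessels of both kidneys were clamped for 30 min and the kidneys were taken 24 h after the clamps were released. Every library was assigned to its group from its title and its description. The labels do not say that each library came from a separate animal, so the p-values measure the spread between these libraries only. The extraction text of the labels mentions retinas, while the tissue field of every sample gives kidney. A list of 9 retina genes was therefore fixed, but none of them reached the expression filter, and the highest group mean was 0.268 FPKM, for Gnat1 in cKO IR.

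The authors deposited 1 table of FPKM (fragments scaled to gene length and library size) with 56748 genes, 1 column per library and the length of each gene model. Per the labels, the authors aligned with HISAT2 2.2.1 and named the builds mm8 and mm9; the counting program, the annotation and any filter are not given in the sources used here. FPKM multiplied by gene length was a whole multiple of 1 step per library in every library, with a largest distance from a whole number of 2.97e-09, which gave the reads behind each value. These sums were 13187531 to 15962303 reads per library. The library size by which the values had been divided was 0.933 to 1.126 times that sum, a factor that differed between libraries. The gene coordinates of the table carry no build name. Of 52036 nuclear genes that share an identifier with GENCODE mouse release 21, 1435 (2.76%) had the same start and end there, so coordinates are given as deposited and their build was not established. A total of 882 symbols occur more than once, and genes were tracked by identifier.

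Before the data were examined, the groups, the tests, the alternatives, 27 gene lists and the rule for the genes named were fixed. FPKM as deposited were transformed as log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the 12 libraries were tested, which left 12868. Fold changes on this scale understate the change of genes with low FPKM. For lists formed for the closer looks at the end, medians over all members used log2(FPKM + 0.1) instead. A linear model with 1 mean per group was fitted in limma 3.58.1 under R 4.3.3, with variances moderated along a trend in mean expression (8 residual and 2.59 prior degrees of freedom). The 5 comparisons were IR against sham within each genotype, cKO against WT within each surgery, and the difference between the genotypes in the effect of IR (the interaction). All tests were two-sided. A gene was called where the p-value adjusted by the Benjamini-Hochberg method over all tested genes was under 0.05. Krt20 and Prdx2 were also compared by an exact permutation test on their FPKM, which with 3 libraries against 3 cannot give a p-value below 0.1.

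Gene lists were tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the 24 lists with tested members within each comparison. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance one way, were run beside it. Camera compares a list with the other genes, whereas fry does not. Where many genes changed, as with IR, a pass by fry is therefore less telling. The lists for lymphocytes and NK cells, urothelium and retina had no tested member, with highest group means of 1.94 FPKM (Trac), 0.717 FPKM (Krt5) and 0.268 FPKM. Members called within a list were counted with the adjustment over all genes and adjusted over the list alone. The genes named are Krt20 and Prdx2 in every comparison. For WT IR against WT sham and for cKO IR against WT IR they also include the 12 called genes with the largest change in each direction, among genes with group values that do not overlap and symbols that are not clone names. The top 5 in each direction were taken for the other comparisons, without the overlap criterion for the interaction. Where no gene was called, the 5 genes in each direction with the smallest p-values were taken. Up to 4 members per list with the smallest p-values were added, and any member of the ferroptosis, peroxiredoxin and keratin lists.

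With 3 reads, the level a library with no read allows for a gene model of 1 kb was 0.176 to 0.226 FPKM, and for Krt20 0.0916 to 0.117 FPKM. Ratios of reads carry a 95% interval from the exact binomial (Clopper-Pearson) method on the reads. Such intervals and limits cover counting error only, since reads without molecular identifiers are not independent molecules. The test was checked on simulated data with the depth of these groups. The simulated spread followed a trend in mean reads within each group. Genes were drawn independently, so shifts shared by many genes of a library were left out. The shares below may therefore not hold for the real data. For changes planted at 4-fold in 100 genes it called 87% to 98%, and at 2-fold it called 26% to 67%. Between 0 and 38 unchanged genes were called in a comparison. The 38 were in cKO IR against WT IR, beside 62% of the genes planted at 2-fold and 95% of those at 4-fold. In WT IR against WT sham 21 unchanged genes were called, beside 58% and 98%. In these comparisons false calls thus took a larger share than the threshold on the adjusted p aims for.

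The alternatives tried were median-ratio and quantile scaling, pseudocounts of 0.1 and 0.5, no filter and a minimum mean of 5 FPKM, an added minimum of a 2-fold change, variances without a trend or estimated robustly, weights per library, a block for the replicate number, a fit on only the groups compared, and leaving out each library. A pair of alternatives was added after the data had been seen: limma's voom on the recovered reads, and scaling to plain library totals. A further alternative, a test for raw counts, was planned only for a table of counts and was not run on the recovered reads. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.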

Results

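Gene expression was measured by RNA sequencing in mouse kidney in 4 groups of 3 libraries: WT sham, WT IR, cKO sham and cKO IR. Per the labels, Krt20, which encodes a keratin of intermediate filaments, was deleted in renal proximal tubular cells of the cKO mice, and IR is bilateral clamping of the renal vessels followed by reperfusion, a model of acute kidney injury. The 12 libraries held 13187531 to 15962303 recovered reads each, and 22681 to 23705 genes had a read in a library. Mitochondrial genes took 7.29% to 10.4% of the reads, and the top 10 genes of a library took 11.8% to 14.1%. Pearson's r across genes between libraries of 1 group lay between 0.9445 and 0.9854. The lowest value was between WT IR 2 and WT IR 3.

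Krt20 (ENSMUSG00000035775, chromosome 11, 99319229 to 99328976, minus strand) was near absent in sham kidneys and abundant after IR in both genotypes. Its reads numbered 1, 0 and 4 in the 3 WT sham libraries and 1, 0 and 0 in the 3 cKO sham libraries. In WT IR there were 2751, 1844 and 1714 reads, or 69.6 ± 12.7 FPKM (SD, n = 3). In cKO IR there were 869, 1061 and 1399 reads, or 36.9 ± 9.47 FPKM (SD, n = 3). The ratio of WT IR to WT sham was 1116 (95% counting interval 478 to 3437), and that of cKO IR to cKO sham, which rests on 1 sham read, was 3141 (563 to 124106). The ratio of cKO IR to WT IR was 0.524 (0.503 to 0.547), and the highest cKO IR library, at 47.0 FPKM, lay below the lowest WT IR library, at 59.9 FPKM. In limma the log2 difference was −0.91 (SE 0.17, adjusted p = 0.132), which did not pass, and the exact permutation test gave p = 0.1, the smallest it can give. Krt20 was 0.0650 ± 0.0816 FPKM in WT sham and 0.0114 ± 0.0198 FPKM in cKO sham (SD, n = 3), a difference not detectable at this depth. The values sum over the gene model, and the table does not separate the deleted part of the gene from the rest, or reads by cell type.

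Prdx2 (ENSMUSG00000005161, chromosome 8, 85696216 to 85701463, plus strand), a peroxiredoxin that reduces peroxides and the protein named in the title of the series, had means of 47.7 ± 2.47 FPKM in WT sham, 42.4 ± 3.82 in WT IR, 43.7 ± 0.855 in cKO sham and 45.7 ± 3.61 in cKO IR (SD, n = 3). No comparison called it: the log2 differences were −0.17 for IR in WT, 0.06 for IR in cKO, −0.12 for cKO against WT in sham, 0.11 for cKO against WT in IR and 0.23 for the interaction, with adjusted p of 0.13, 0.581, 0.688, 0.59 and 0.409. In the exact permutation test the first 4 gave p = 0.2, 0.5, 0.1 and 0.3, where 0.1 is the smallest it can give. The sham groups did not overlap, at 45.2 to 50.1 FPKM in WT and 42.7 to 44.2 FPKM in cKO. These are RNA levels of whole kidney, and protein or exosome content was not measured in these libraries.

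**Figure D1:**
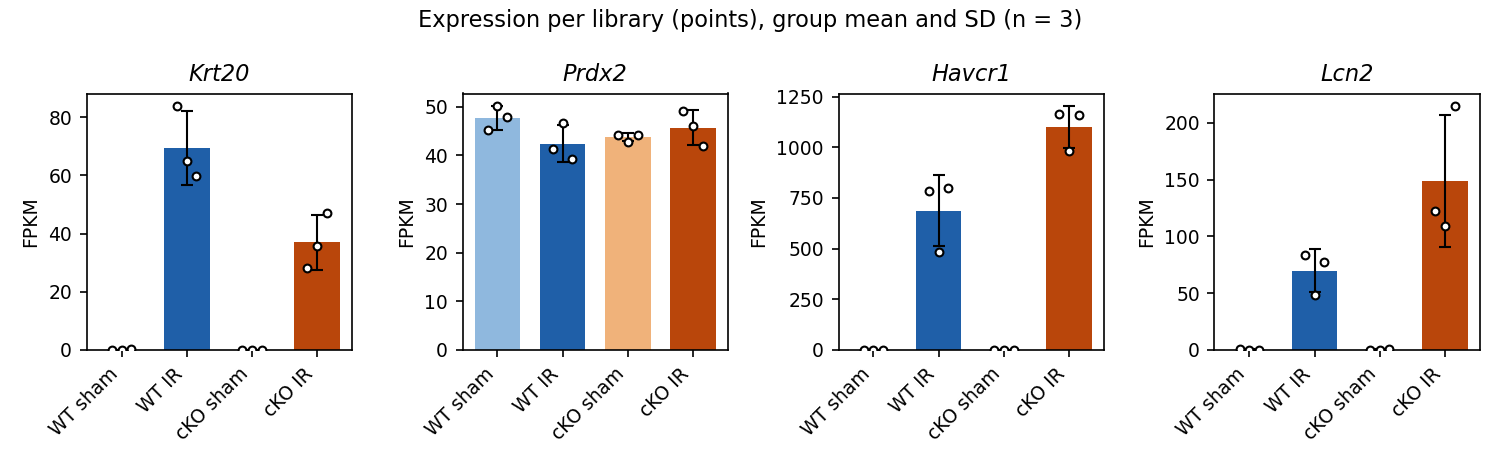
FPKM of Krt20, Prdx2, Havcr1 and Lcn2 in each of the 12 libraries (points), with group means (bars) and SD (error bars, n = 3). Krt20 averaged 69.6 FPKM in WT IR and 36.9 FPKM in cKO IR, while Havcr1 averaged 688 and 1101 FPKM in the same groups and Prdx2 stayed between 42.4 and 47.7 FPKM in all 4.

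The effect of injury in wild type kidneys was asked by WT IR against WT sham. Tubular injury markers rose and proximal tubule genes fell. Havcr1, which encodes the injury marker KIM-1, went from 0.397 ± 0.129 to 688 ± 176 FPKM (SD, n = 3; log2 difference 8.91, SE 0.22, adjusted p = 7.78e-09). Spp1, which encodes the matrix protein osteopontin, went from 335 ± 15.2 to 8002 ± 2171 FPKM. Among the largest increases were also Lcn2, which encodes an iron-siderophore-binding protein released by injured tubules (log2 difference 5.66), the cornified envelope gene Sprr1a (5.39) and the fibrinogen chains Fgg (5.37), Fgb (4.53) and Fga (4.21). The glutathione transferase Gsta1 (4.18), the neutrophil chemokine Cxcl1 (4.14), the protease inhibitor Timp1 (4.01) and complement C3 (3.93) rose as well. Egf, the growth factor made by the distal nephron, fell from 169 ± 10.5 to 7.59 ± 9.61 FPKM (log2 difference −4.92, SE 0.58, adjusted p = 0.000149). Other large decreases were in the organic anion transporter Slc22a7 (−4.29), the brush border protease Mep1b (−4.08), the methyltransferase Inmt (−4.01) and the amino acid transporter Slc7a13 (−3.75). Cyp7b1 (−3.54) and Scd1 (−3.32), enzymes of sterol and fatty acid metabolism, Mettl7a2 (−3.40), Serpina1d (−3.23), Akr1c14 (−3.22), Wfdc15b (−3.19) and BC024386 (−3.08) completed the 12 largest decreases. In all, 5424 of 12868 genes were called, 2910 higher and 2514 lower, and 481 of the higher and 603 of the lower ones changed at least 2-fold. Scaling to plain library totals moved the median of all genes by 0.13 on the log2 scale and gave 4160 higher and 1845 lower, so the balance of directions depended on the scaling.

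By list, all 21 tested tubular injury markers rose in WT IR (median log2 difference 2.67, adjusted p = 7.05e-15 by camera, and 0.185 with an estimated correlation). Of 28 proximal tubule genes 24 fell and 4 did not pass (median −1.41, adjusted p = 2.01e-10, and 0.302 with an estimated correlation), with Ass1, of arginine synthesis, at −2.30, the inositol oxygenase Miox at −2.54 and the glucose-6-phosphatase G6pc at −2.34. Of 10 genes of the thick ascending limb and distal convoluted tubule 9 fell (10 adjusted over the list alone; adjusted p = 2.54e-05, and 0.302 with an estimated correlation), among them Pvalb at −2.80 and the loop diuretic target Slc12a1 at −2.70. In the collecting duct list 5 of 12 fell (adjusted p = 0.00271, and 0.302 with an estimated correlation), including the water channels Aqp3 at −1.29 and Aqp4 at −1.64. Fatty acid oxidation and peroxisome genes fell in 13 of 22 (14 adjusted over the list alone; adjusted p = 0.000126, and 0.431 with an estimated correlation), including Cpt1a, the entry enzyme of mitochondrial fatty acid import, at −0.88. Oxidative phosphorylation and TCA cycle genes fell in 17 of 23 (18 adjusted over the list alone; adjusted p = 2.54e-05, and 0.431 with an estimated correlation), with Ndufs1 and Sdha both at −0.79. Cell cycle genes rose in 12 of 13 (adjusted p = 1.55e-08, and 0.302 with an estimated correlation), led by the DNA replication helicase genes Mcm5 (2.90), Mcm3 (2.48) and Mcm4 (2.26). Keratin and desmosome genes rose in 9 of 11 (adjusted p = 2.54e-05, and 0.185 with an estimated correlation), among them the simple epithelial keratins Krt8 (2.23), Krt18 (4.53 to 28.7 FPKM) and Krt19 (1.95). Of 15 genes for cytokines and NF-kB targets 11 rose (adjusted p = 5.76e-05, and 0.316 with an estimated correlation), as did 11 of 17 immediate early and heat shock genes, of which 1 fell (adjusted p = 0.000265, and 0.302 with an estimated correlation). In the necroptosis, pyroptosis and apoptosis list 7 of 17 rose (8 adjusted over the list alone; adjusted p = 0.019, and 0.431 with an estimated correlation), with the TWEAK receptor Tnfrsf12a at 3.56, and 7 of 15 fibrosis and matrix genes rose (adjusted p = 0.00411, and 0.431 with an estimated correlation), with Ccn1 at 2.58.

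Ferroptosis suppressor genes rose in 8 of 20 and fell in 2 (8 and 3 adjusted over the list alone; median 0.13, adjusted p = 0.0424, and 0.302 with an estimated correlation). The call was lost without WT IR 2 (adjusted p = 0.149) or without WT sham 3 (adjusted p = 0.0504). The heavy and light ferritin chains that store iron, Fth1 and Ftl1, rose by 0.89 and 0.95, the chaperone Hspb1 by 3.07 and the quinone reductase Nqo1 by 1.01. Scd1, also on this list, was 1 of the 2 that fell, at −3.32 (adjusted p = 0.00229 in limma). Gpx4, the enzyme that reduces lipid hydroperoxides, was at −0.08 (adjusted p = 0.684). Ferroptosis drivers and markers did not pass as a list (adjusted p = 0.19), with 7 of 17 higher and 5 lower (9 and 5 adjusted over the list alone). Of these, the heme oxygenase Hmox1 rose by 2.68, the transferrin receptor Tfrc by 1.24 and Acsl4, which activates polyunsaturated fatty acids, by 1.10. Among peroxiredoxins and antioxidant enzymes 4 of 19 rose and 6 fell (4 and 7 adjusted over the list alone; adjusted p = 0.468), with the sulfiredoxin Srxn1 at 1.85, thioredoxin Txn1 at 0.98 and Prdx6 at 0.55, against Sod2 at −0.90 and Cat at −0.66. Exosome biogenesis and release genes rose in 10 of 21 and fell in 1 (adjusted p = 0.00349, and 0.302 with an estimated correlation), with the ESCRT-associated Pdcd6ip at 0.73 and the tetraspanin Cd9 at 1.03. Glycolysis and hypoxia genes rose in 6 of 18 and fell in 4 (median 0.08, mean −0.03, adjusted p = 0.725).

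Markers of blood cells moved with injury too. Of 4 neutrophil genes 3 rose (4 adjusted over the list alone; adjusted p = 0.0236, and 0.429 with an estimated correlation), with S100a9 at 5.32 to 26.3 FPKM in WT IR and 0.663 to 1.28 FPKM in WT sham. All 5 red blood cell genes fell (median −1.83, adjusted p = 0.0245, and 0.431 with an estimated correlation), a call lost without WT IR 1 (adjusted p = 0.0547) or WT IR 2 (0.069), and Hbb-bs was 428 FPKM in WT sham 3 against 134 and 154 FPKM in the other WT sham libraries. Cfd, a fat marker, was 0 FPKM in WT IR 1 and 5.51 and 7.52 FPKM in WT IR 2 and WT IR 3; its call (log2 difference 1.89) was kept only without WT IR 1, and leaving out any other library of the pair of groups gave an adjusted p of 0.0609 to 0.108. The lists for macrophages (1 of 9 higher, 1 lower), endothelium (1 of 9 lower, 0 adjusted over the list alone), podocytes (2 of 7 lower), stroma (1 of 7 lower) and fat and adrenal tissue (1 of 3 higher) did not pass, at adjusted p of 0.604, 0.124, 0.392, 0.585 and 0.585. Of the 16 lists that passed, none did by camera with an estimated correlation, where the smallest adjusted p was 0.185. The fry test, which does not compare a list with the other genes, passed 17. WT IR 2 lay between the sham libraries and the other WT IR libraries, at 9.8 on the first principal component against 34.9 and 42.1, and without it 6047 genes were called.

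**Figure D2:**
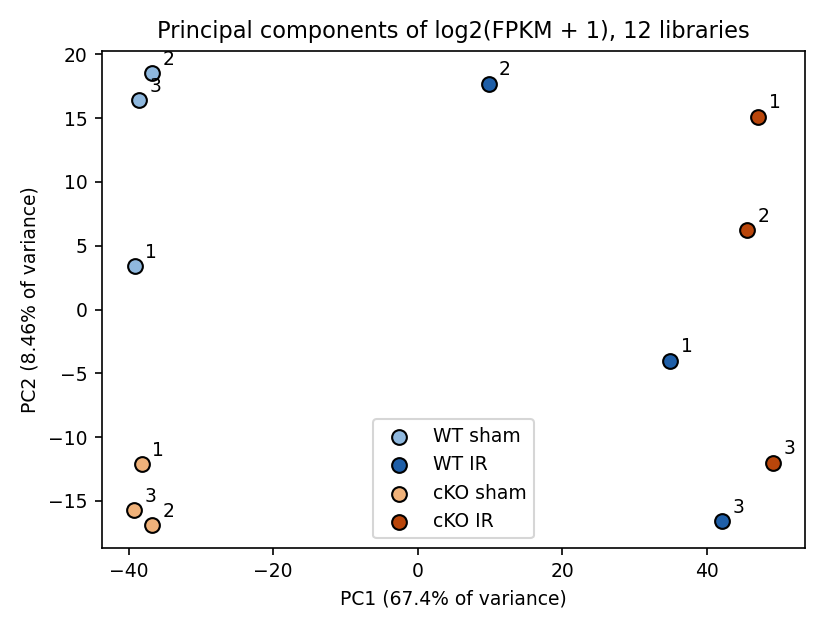
First and second principal components of log2(FPKM + 1), with 67.4% and 8.46% of the variance, for the 12 libraries (points, numbered by replicate and coloured by group). The sham libraries sit between −39.2 and −36.7 on the first component, the cKO IR libraries between 45.5 and 49.1, and WT IR 2 at 9.8.

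The effect of injury in the cKO genotype was asked by cKO IR against cKO sham. Havcr1 rose from 0.769 ± 0.480 to 1101 ± 104 FPKM (SD, n = 3; log2 difference 9.32, SE 0.22, adjusted p = 4.89e-09), and Lcn2 (6.69), Sprr1a (5.68), Fgb (5.32) and Krt20 (5.20) followed. Egf fell by 5.87 on the log2 scale. A set of immune GTPase genes also fell, from a high level in cKO sham: Tgtp1 (−5.61), Iigp1 (−5.28) and Igtp (−5.02), together with BC023105 (−5.96), annotated in the table as a processed pseudogene. Igtp went from 224 ± 43.3 to 5.96 ± 1.56 FPKM. In all, 6538 genes were called, 3571 higher and 2967 lower, with 737 and 902 of them changed at least 2-fold.

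Tubular injury markers rose in 20 of 21 in cKO IR (21 adjusted over the list alone; median log2 difference 3.50, adjusted p = 2.22e-12, and 0.212 with an estimated correlation). Proximal tubule genes fell in 26 of 28 (median −1.54, adjusted p = 1.9e-10, and 0.318 with an estimated correlation), with Miox at −3.18, Gatm, of creatine synthesis, at −3.14 and the lactate transporter Slc5a12 at −2.27. All 10 genes of the thick ascending limb and distal convoluted tubule fell (adjusted p = 7.11e-05, and 0.277 with an estimated correlation), as did 8 of 12 collecting duct genes (10 adjusted over the list alone; adjusted p = 0.000145, and 0.22 with an estimated correlation). Oxidative phosphorylation and TCA cycle genes fell in 11 of 23 and rose in 1 (adjusted p = 0.00203, and 0.643 with an estimated correlation). Fatty acid oxidation genes did not pass as a list (5 of 22 lower, 1 higher, and 5 and 0 adjusted over the list alone; median 0.01, mean −0.09, adjusted p = 0.287), although the regulator Ppargc1a fell by 1.18 and Acadm by 1.39. Rises were counted in 14 of 17 immediate early and heat shock genes (15 adjusted over the list alone; adjusted p = 9.9e-06, and 0.212 with an estimated correlation), with Myc at 3.71 and Maff at 2.87, in 11 of 15 genes for cytokines and NF-kB targets, with 1 lower (adjusted p = 0.00203, and 0.492 with an estimated correlation), and in 10 of 11 keratin and desmosome genes (adjusted p = 7.11e-05, and 0.212 with an estimated correlation). Cell cycle genes rose in 9 of 13 and fell in 1 (9 and 2 adjusted over the list alone; adjusted p = 0.0123, and 0.569 with an estimated correlation). Ferroptosis suppressors rose in 11 of 20 and fell in 2 (adjusted p = 0.0127, and 0.231 with an estimated correlation), with Nqo1 at 2.24, the glutathione reductase Gsr at 1.17 and Fth1 at 1.17. Drivers and markers rose in 9 of 17 and fell in 6 (adjusted p = 0.287), with Hmox1 at 3.42 and Acsl4 at 1.47. Antioxidant enzymes rose in 7 of 19 and fell in 4 (adjusted p = 0.764), with Srxn1 at 3.04 and the thioredoxin reductase Txnrd1 at 1.73. Exosome genes rose in 15 of 21 and fell in 2 (adjusted p = 0.00117, and 0.212 with an estimated correlation), with Cd9 at 1.29 and Pdcd6ip at 0.91.

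In the cell death list 10 of 17 rose and 1 fell in cKO IR (adjusted p = 0.0144, and 0.492 with an estimated correlation), with Tnfrsf12a at 4.41, and 6 of 15 fibrosis and matrix genes rose (adjusted p = 0.0075, and 0.556 with an estimated correlation), a call lost without cKO IR 3 (adjusted p = 0.0613). Glycolysis and hypoxia genes rose in 9 of 18 and fell in 3 without passing as a list (adjusted p = 0.138). The 4 neutrophil genes rose, without the list passing (adjusted p = 0.0733), and none of 5 red blood cell genes did (adjusted p = 0.287). Macrophages (2 of 9 higher, 1 lower), endothelium (2 of 9 lower, 1 adjusted over the list alone), podocytes (1 of 7 lower), stroma (2 of 7 lower) and fat and adrenal tissue (0 of 3) did not pass, at adjusted p of 0.764, 0.179, 0.287, 0.287 and 0.764. None of the 13 lists that passed did so with an estimated correlation (smallest adjusted p = 0.212 with an estimated correlation), while fry passed 15. Across genotypes, 2446 genes rose in both and 1922 fell in both, against 807.6 and 579.7 if the calls were independent, and 39 were called in opposite directions. Pearson's r of the pair of IR effects across genes was 0.823, although genes are not independent replicates. Among genes called in both, the median absolute log2 difference was 0.609 in WT and 0.709 in cKO, and 68.5% changed more in cKO, but without WT IR 2 these were 0.678, 0.709 and 54.5%.

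The question whether the uninjured kidney differs in the cKO genotype was asked by cKO sham against WT sham. The make-up of the libraries also differed without overlap. Mitochondrial genes took 9.82% to 10.4% of the reads in WT sham and 8.11% to 8.47% in cKO sham. The top 10 genes took 13.6% to 14.1% and 12.2% to 12.5%. Whether this bears on the calls was not tested. A group of immune GTPase genes was far higher in cKO sham. Tgtp1 went from 2.05 ± 1.55 to 91.1 ± 22.5 FPKM (SD, n = 3; log2 difference 5.01, SE 0.37, adjusted p = 0.000208), Iigp1 from 4.40 ± 2.87 to 96.5 ± 29.3 FPKM (4.26) and Igtp from 14.6 ± 6.92 to 224 ± 43.3 FPKM (3.92). Irgm2, of the same GTPase family, rose by 3.44, and BC023105 by 5.20. The immunoglobulin genes Igkc, the kappa light chain (log2 difference −3.38), and Igha, the IgA heavy chain, were lower, from 18.8 ± 6.07 to 0.981 ± 0.955 FPKM and from 7.81 ± 1.42 to 0.0943 ± 0.104 FPKM. WT sham 1 was the highest WT sham library for the GTPases, with Igtp at 22.5 FPKM against 11.3 and 9.92 FPKM in the others. The 7 genes above kept their calls whichever of the 6 sham libraries was left out. Pdk4, an inhibitor of pyruvate use that responds to fasting, was lower by −2.21 (20.6 ± 3.27 against 3.64 ± 0.523 FPKM), a call lost without WT sham 2 (adjusted p = 0.050023) or cKO sham 2 (0.0536). The vitamin D hydroxylase Cyp24a1 (−2.71) and Azgp1 (−2.12) were called with all libraries, but leaving out any 1 of the 6 sham libraries raised their adjusted p to between 0.0785 and 0.141 and between 0.0758 and 0.109. In all, 142 genes were called, 109 higher and 33 lower, with 74 and 15 of them changed at least 2-fold. The fit on only the groups compared gave 137 higher and 114 lower, and array weights 373 and 259. Under the other alternatives 68.5% to 84.1% of the called genes were higher. The count was 55 without WT sham 2, 73 without WT sham 3, 56 without cKO sham 2 and 68 without cKO sham 3.

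Few genes of the fixed lists differed between the sham groups. Tubular injury markers were higher on balance (median log2 difference 0.21, adjusted p = 0.0115, and 0.916 with an estimated correlation), with Fgg at 1.89 and Spp1 at 1.07 called of 21 (3 adjusted over the list alone). The list lost its call without WT sham 3 (adjusted p = 0.0774). Fgg lost its call without WT sham 2, WT sham 3, cKO sham 2 or cKO sham 3 (adjusted p of 0.0619, 0.0544, 0.0734 and 0.0682), and Spp1 without any 1 of the 6 sham libraries (0.0702 to 0.109). Fatty acid oxidation genes were lower (median −0.23, adjusted p = 0.000771) and cell cycle genes higher (median 0.38, adjusted p = 0.00111), both with no member called (0 of 22 and 3 of 13 adjusted over the list alone). Both had adjusted p = 0.916 with an estimated correlation, and fry passed no list in this comparison. The cell cycle list also lost its call under a minimum mean of 5 FPKM. Examples that did not pass were Cpt1a at −0.42 and Cdc20, a mitotic activator, at 0.85 (adjusted p = 0.164 and 0.103). The chemokine Cxcl10 (2.51), C3 (1.66) and the apoptosis effector Bak1 (0.69) were called higher and the oxygen sensor Egln3 (−1.10) lower. Of these calls, none was kept without WT sham 2, where the adjusted p were 0.0977, 0.170, 0.0598 and 0.106. No member of the ferroptosis, antioxidant, exosome or keratin lists was called, nor any of the cell type lists, and the list tests of these ranged from adjusted p = 0.0742 for red blood cells to 0.848 for the collecting duct. The median and the direction of the test differed for the cell death list (−0.02, upward) and for stroma (−0.03, upward). Red blood cell genes (median −0.86) passed without WT sham 1 (adjusted p = 0.0179), WT sham 2 (0.0133) or cKO sham 2 (0.0329).

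**Figure D3:**
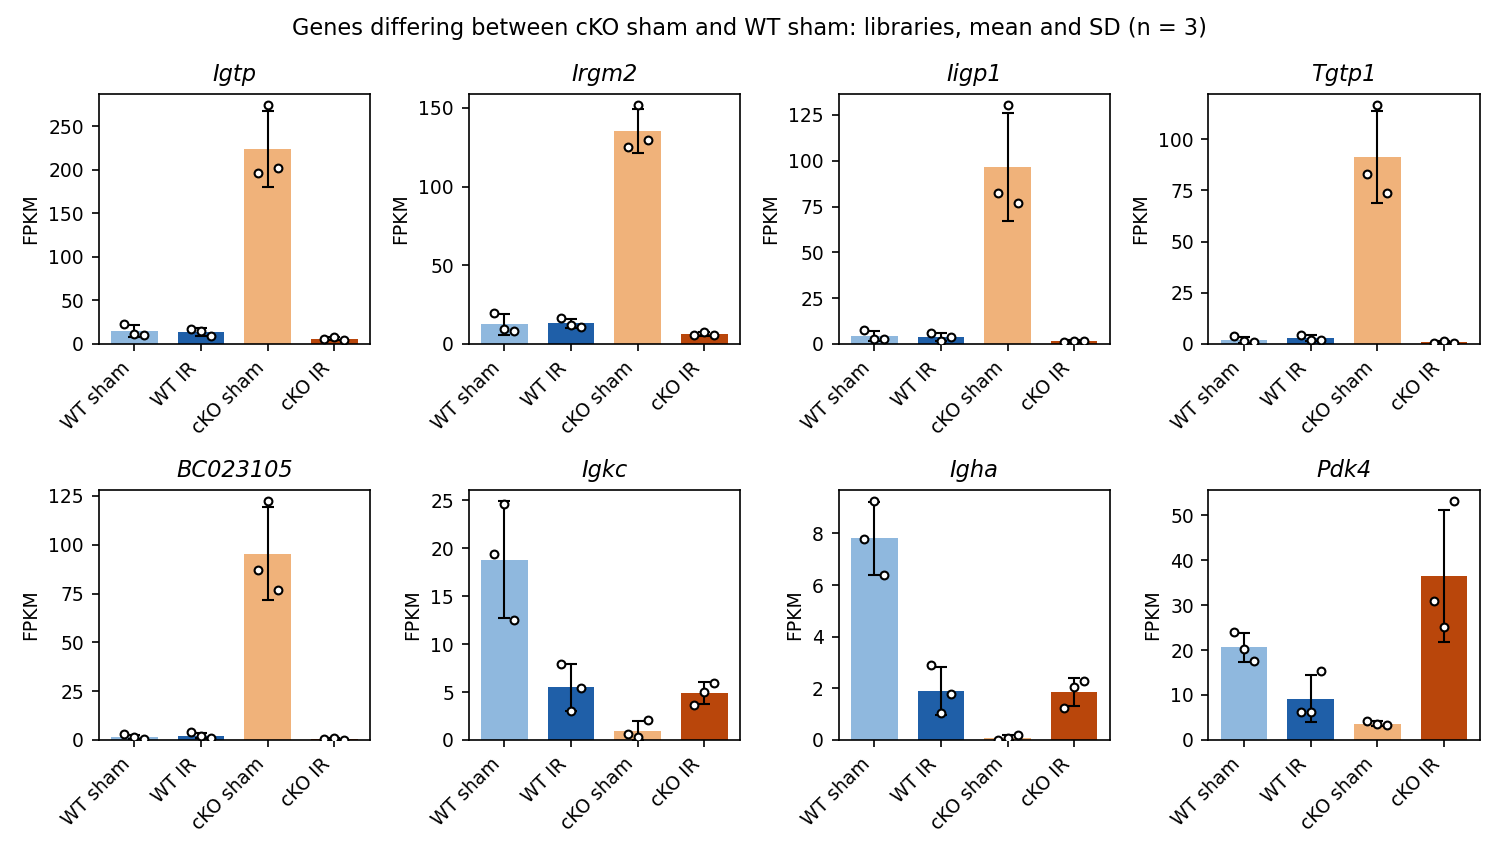
FPKM of 8 genes in each of the 12 libraries (points), with group means (bars) and SD (error bars, n = 3). Igtp, Irgm2, Iigp1, Tgtp1 and BC023105 are high in cKO sham alone, with Igtp at 224 FPKM against 5.96 to 14.6 FPKM in the other groups, and Igkc, Igha and Pdk4 are lowest in cKO sham.

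Whether the injured kidney differs in the cKO genotype, the question of the design, was asked by cKO IR against WT IR. No single gene passed in limma (0 of 12868), and voom on the recovered reads called 1. An unadjusted p under 0.05 in limma was found for 1926 genes, against 643.4 if the p-values were well calibrated. The fit shared 1 spread per gene over all groups, although the WT IR libraries agreed less well than the sham libraries. In the simulation 38 unchanged genes were called in this comparison. The excess thus does not by itself show changed genes. With no filter 9 genes were called, and array weights, in a fit that stopped before it converged, called 1544, Krt20 among them (adjusted p = 0.00119). The gene called by voom was Pdp2, a phosphatase that activates pyruvate dehydrogenase, with the smallest adjusted p of the comparison in limma as reported (0.0513) and means of 8.75 ± 0.705 FPKM in WT IR and 4.38 ± 0.732 FPKM in cKO IR (SD, n = 3; log2 difference −0.86). The other genes with the smallest p-values, none of which passed (adjusted p = 0.132), were the transcription factor Maff (1.14), the elongation factor Ell (0.64), the apoptosis inhibitor Bcl2l1 (0.58), Tmcc3 (0.45) and Lrrfip2 (0.45) on the higher side. On the lower side they were Clec2h (−1.55), Gm12208 (−1.28), Krt20 (−0.91) and the nucleotide synthesis gene Prps2 (−0.41). The count of called genes was 12 without WT IR 1, 2 without WT IR 3, 1 without cKO IR 1, 4 without cKO IR 2 and 0 without WT IR 2 or cKO IR 3.

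By camera at the preset correlation, injury markers as a group were higher and cell cycle genes lower in cKO IR than in WT IR. The correlations estimated for these lists were 0.31 and 0.66, and neither list passed with them. Neither passed by fry (adjusted p = 0.0981 and 0.0724), so the group differences rest on the preset correlation. Tubular injury markers had a median log2 difference of 0.54, with 20 of 21 above 0 and Krt20 the exception (adjusted p = 1.32e-05 by camera, adjusted p = 0.343 with an estimated correlation). Adjusted over the list alone, 11 were higher and 1 lower. Lcn2 was 69.9 ± 18.7 FPKM in WT IR and 149 ± 57.9 FPKM in cKO IR (log2 difference 1.05, adjusted p = 0.169). Cell cycle genes had a median of −0.50, with 0 of 13 above 0 and 10 lower adjusted over the list alone (adjusted p = 4.8e-10, and 0.269 with an estimated correlation). Mcm6 stood at −0.64, Mcm5 at −0.56, the transcription factor E2f1 at −0.55 and the topoisomerase Top2a at −0.71. These lists kept their calls whichever of the 6 IR libraries was left out. Ferroptosis suppressors were higher on balance (median 0.19, 18 of 20 above 0, adjusted p = 0.002, and 0.269 with an estimated correlation; 3 adjusted over the list alone), with Gsr at 0.54, Nqo1 at 0.59, Ftl1 at 0.37 and Gpx4 at 0.03. Exosome biogenesis and release genes were higher too (median 0.16, 16 of 21 above 0, adjusted p = 0.00154, and 0.269 with an estimated correlation; 0 adjusted over the list alone), with the exosome cargo adaptor partner Sdc4 at 0.42 and Pdcd6ip at 0.23. For these lists and for glycolysis and hypoxia, fry gave adjusted p of 0.0126, 0.0126 and 0.0298, and it passed no other list. Ferroptosis drivers and markers did not pass (median 0.11, adjusted p = 0.361), with Hmox1 at 83.8 ± 37.7 FPKM in WT IR and 193 ± 72.7 FPKM in cKO IR (log2 difference 1.22, adjusted p = 0.175) and Acsl4 at 0.55 (adjusted p = 0.201). Peroxiredoxins and antioxidant enzymes did not pass either (median 0.11, adjusted p = 0.0677; 2 of 19 higher adjusted over the list alone), with Srxn1 at 1.03 and Txnrd1 at 0.75. This list passed without WT IR 2 (adjusted p = 0.00249), cKO IR 2 (0.0335) or cKO IR 3 (0.00628).

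Collecting duct genes were lower in cKO IR (median −0.18, 0 of 12 above 0, adjusted p = 0.00059, and 0.271 with an estimated correlation; 2 lower adjusted over the list alone), with the cortisol-inactivating enzyme Hsd11b2 at −0.50. Proximal tubule genes were lower (median −0.38, adjusted p = 1.1e-06, and 0.561 with an estimated correlation; 3 of 28 adjusted over the list alone), with Gatm at −1.22, the phosphate transporter Slc34a1 at −1.16 and Slc5a12 at −1.01. Without WT IR 2 this median was −0.13 (adjusted p = 0.137). Immediate early and heat shock genes were higher (median 0.52, adjusted p = 0.0495, and 0.649 with an estimated correlation; 1 of 17 adjusted over the list alone), a call lost without WT IR 2 (adjusted p = 0.165), cKO IR 2 (0.246) or cKO IR 3 (0.0701). Glycolysis and hypoxia genes were higher (median 0.17, adjusted p = 0.0172, and 0.269 with an estimated correlation; 2 of 18 adjusted over the list alone), with the glucose transporter Slc2a1 at 0.78 and the peptide hormone gene Adm at 0.75. That call was lost without WT IR 1 (0.0616), WT IR 3 (0.0606) or cKO IR 3 (0.0599). Oxidative phosphorylation genes had a median of 0.02 while camera ranked them downward (adjusted p = 0.707), and the median was 0.14 without WT IR 2 (adjusted p = 0.00148) and −0.10 without WT IR 3 (0.00783). Neutrophil genes had a median of −0.04 (adjusted p = 0.795), with S100a9 at 26.3 FPKM in WT IR 3 against 5.32 to 11.9 FPKM in the other IR libraries, and a median of 0.56 without WT IR 3 (adjusted p = 0.029). Keratins and desmosomes had adjusted p = 0.0524, with Krt18 at 0.55 and Krt8 at 0.32. The other lists had adjusted p between 0.0677 and 0.811. Of these, fatty acid oxidation genes (median 0.17) passed without WT IR 2, where their median was 0.38 (adjusted p = 8.07e-09), and without cKO IR 2 (0.22, 0.00701).

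**Figure D4:**
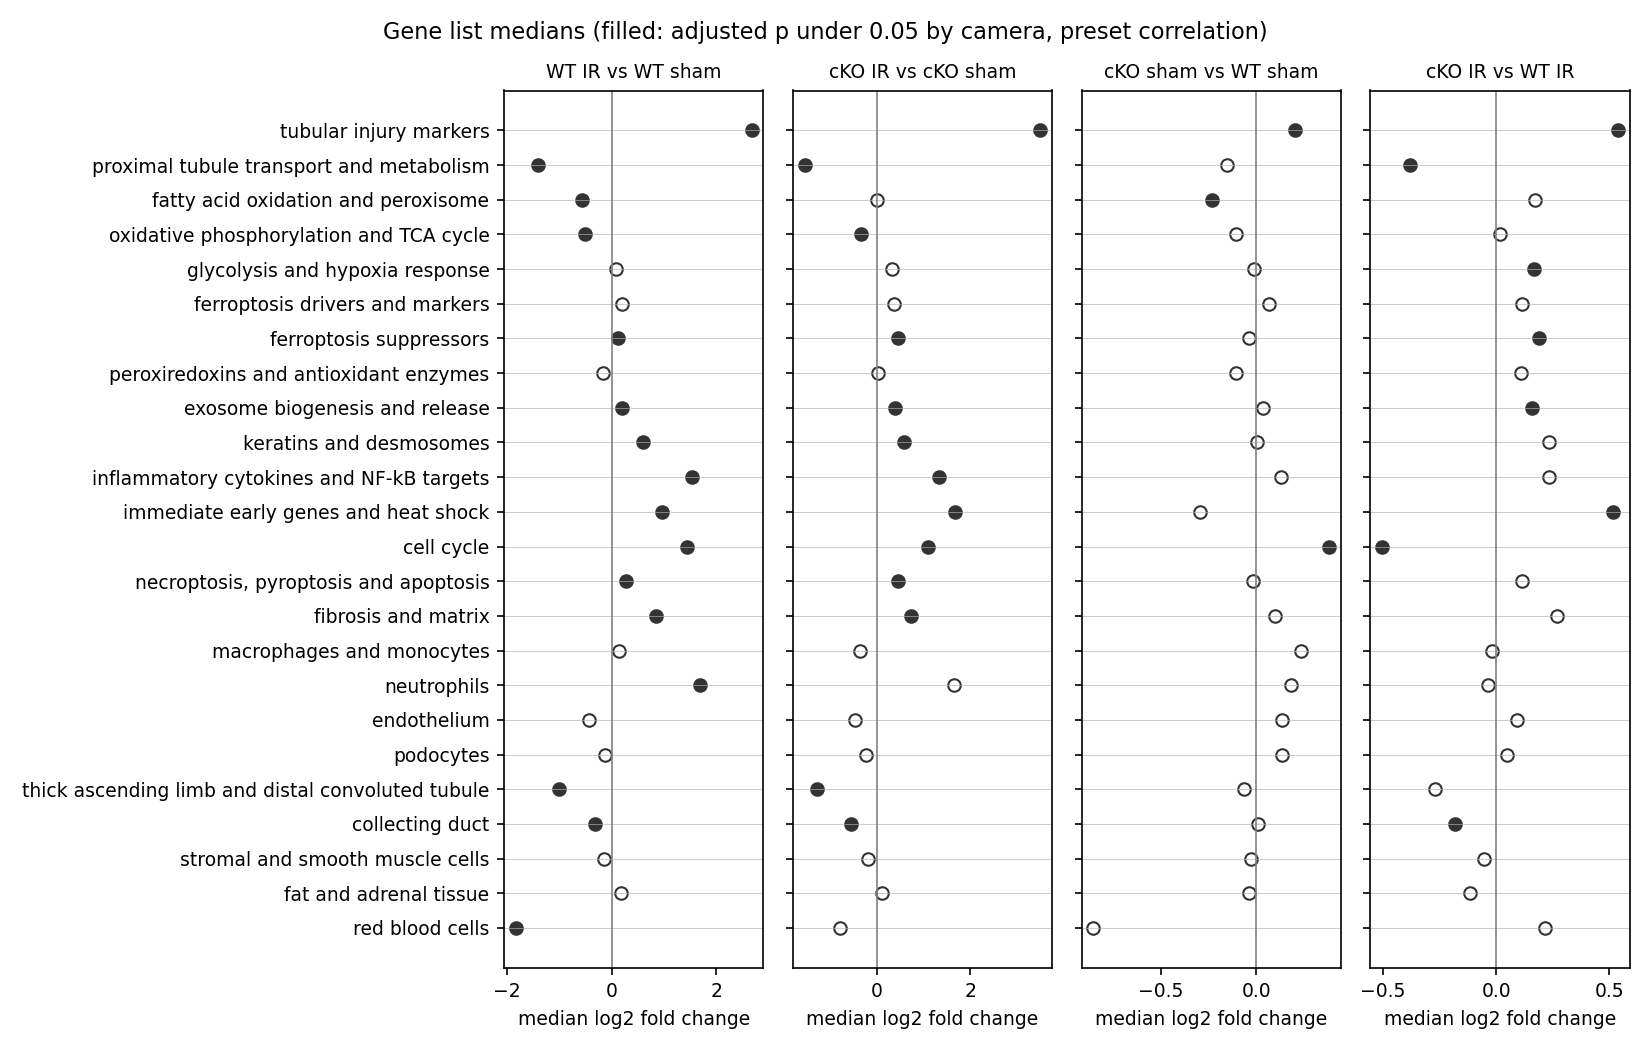
Median log2 fold change (x axis, a separate scale per panel) of 24 gene lists in 4 comparisons, each point 1 list and filled where camera at the preset correlation gave an adjusted p under 0.05. In cKO IR against WT IR, tubular injury markers stand at 0.54 and cell cycle genes at −0.50.

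Whether IR acted differently in the 2 genotypes was asked by the interaction, the IR effect in cKO minus that in WT. It called 113 genes, 38 higher and 75 lower, of which 23 and 64 changed at least 2-fold. The largest were genes that already differed between the sham groups: BC023105 (−6.22), Tgtp1 (−5.98), Iigp1 (−5.18) and Igtp (−5.00, SE 0.43, adjusted p = 0.000804) on the lower side, and Pdk4 (4.13, SE 0.46, adjusted p = 0.00336) and Igha (3.01) on the higher side. Pdk4 went from 20.6 to 9.22 FPKM with IR in WT and from 3.64 to 36.4 FPKM with IR in cKO. These 6 genes kept their calls whichever of the 12 libraries was left out. Igkc (3.29) lost its call without WT sham 2 (adjusted p = 0.0604), cKO sham 1 (0.0515) or cKO sham 2 (0.0563). The transcription factor Irf7 (−4.63) kept its call without WT sham 1 (0.000541) but not without any other library (0.0515 to 0.115), and was 25.2 FPKM in WT sham 1 against 3.85 and 2.56 FPKM in the other WT sham libraries. Cyp24a1 (3.88) kept it without WT IR 1, cKO IR 1 or cKO IR 3 and lost it without any other library (0.0559 to 0.0844), and Depp1 (2.42) kept it without WT sham 3, WT IR 1, cKO sham 1 or cKO IR 1 and lost it without any other (0.0504 to 0.0900). Krt20 was not called (−0.84, SE 0.24, adjusted p = 0.13). The count of called genes was 41 without WT sham 2, 73 without WT sham 3, 71 without cKO sham 1, 43 without cKO sham 2, 62 without cKO sham 3 and 58 without cKO IR 1.

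The IR effect on cell cycle genes was smaller in cKO (median difference −0.89, 0 of 13 above 0, adjusted p = 3.19e-10, and 0.523 with an estimated correlation), with 10 members lower adjusted over the list alone. Its 1 called member was Mcm5, at −1.16, whose call was kept without WT sham 1, WT IR 2, WT IR 3 or cKO IR 2 and lost without any other library (adjusted p of 0.0690 to 0.111). For fatty acid oxidation genes it was less negative in cKO (median 0.43, 20 of 22 above 0, adjusted p = 0.00112, and 0.85 with an estimated correlation), with Cpt1a at 0.70 (adjusted p = 0.0908). Both list calls were kept whichever library was left out. Ferroptosis suppressors (median 0.28, adjusted p = 0.0338), glycolysis and hypoxia genes (0.22, 0.0338), immediate early and heat shock genes (1.10, 0.0184), collecting duct genes (−0.26, 0.0304) and proximal tubule genes (−0.17, 0.0452) also passed. With an estimated correlation their adjusted p were 0.523, 0.523, 0.718, 0.718 and 0.892, and each lost its call without certain libraries. For suppressors these were WT sham 2, WT IR 1, WT IR 3, cKO sham 2 and cKO IR 1 (adjusted p of 0.0583 to 0.0668), and for glycolysis WT sham 2, WT IR 1, WT IR 3, cKO sham 2 and cKO IR 3 (0.0541 to 0.0708). For immediate early genes it was WT IR 2 (0.0625), and for the collecting duct WT sham 1 (0.0658), WT IR 2 (0.0845) and cKO sham 1 (0.102). The proximal tubule list lost its call without WT sham 1, WT sham 2, cKO sham 1, cKO sham 2 or cKO IR 3 (0.0662 to 0.201), and without WT IR 2 its median was 0.14 (0.747). Nqo1 (1.23), the called suppressor, lost its call without WT sham 2, WT sham 3, cKO sham 2, cKO sham 3 or cKO IR 1 (0.0616 to 0.0806), and Maff (1.44), the called immediate early gene, without WT sham 2, cKO sham 2, cKO sham 3 or cKO IR 1 (0.0616 to 0.0748). The other 17 lists did not pass, with adjusted p from 0.0507 for antioxidant enzymes to 0.942 for ferroptosis drivers and markers, and fry passed none. Cytokine and NF-kB target genes had a median of 0.12 but a mean of −0.18.

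**Figure D5:**
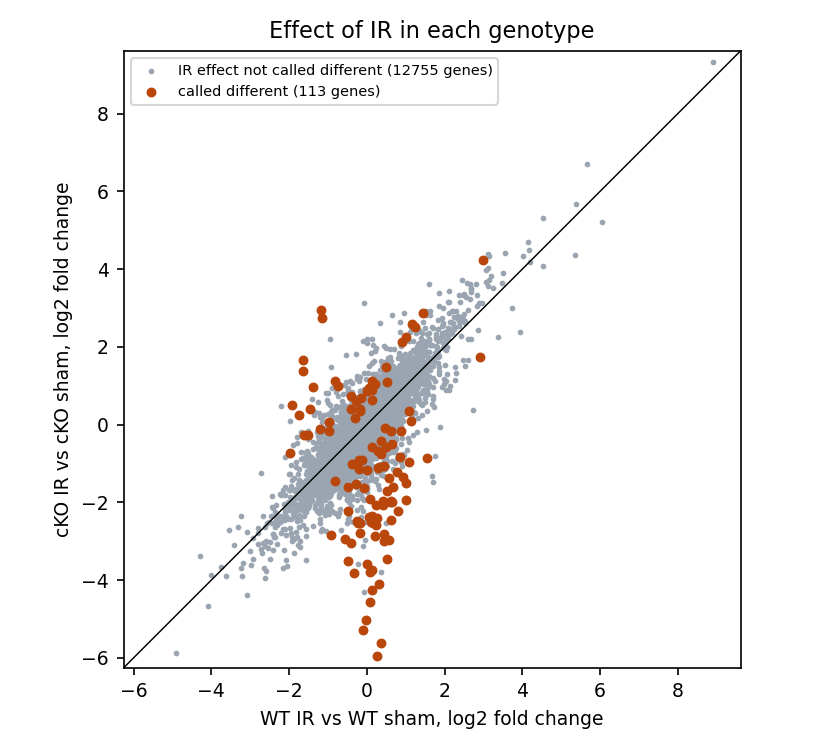
Log2 fold change with IR in cKO (y axis) against that in WT (x axis) for 12868 tested genes (points), with the 113 genes called in the interaction in a darker colour and a line of equal effects. Pearson's r across genes was 0.823, and the 75 genes called lower lie below the line.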

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

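The tests of a genotype effect of the same size in sham and IR, of sham RNA mixed into WT IR 2, of urothelium and of milder injury in cKO IR were chosen only after the results they bear on had been seen. The interaction is the test that brought the results below to attention: the effect of IR differed between cKO and WT for 113 genes. Of 100 splits of the genotypes within surgery, the real one included, 1 gave as many genes, and the highest of the others gave 40. The other splits that kept the 3 WT sham libraries together gave 11 to 40 genes, and the rest gave 0 to 3. Among these splits, counts above 3 thus came only with the real sham grouping, and 113 only with the real IR grouping as well. For either grouping alone, the 10 possible splits are too few to exclude chance. For the other comparisons the 10 splits of 6 libraries are too few for a share under 0.05. The real values and the highest others were 5424 and 3 for IR in WT, 6538 and 2 for IR in cKO, 142 and 1 for cKO against WT in sham, and 0 and 4 for cKO against WT in IR. For the last, any split gives at least as many genes as the real 0, so the splits cannot inform it. For each of the first 3 only the real split gave as many (1 of 10).

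Genes that respond to interferon stood high in cKO sham and gave most of the largest interaction values: BC023105, annotated as a processed pseudogene (−6.22), Tgtp1 (−5.98), Iigp1 (−5.18), Igtp (−5.00) and Irgm2 (−4.39), with Irf7 (−4.63) losing its call without any 1 library other than WT sham 1 (adjusted p of 0.0515 to 0.115). A general rise of immune cells in the cKO sham kidneys is argued against by abundant pan-leukocyte genes, at a median of 0.989 times their WT sham level (interquartile range 0.880 to 1.02, 10 genes). A rise of a small subset was not tested, since the lymphocyte and NK cell list had no tested member. Reads shared between GTPase paralogs as the whole source are argued against by 10 single-copy interferon-inducible genes, with a median log2 difference of 1.60 and all 10 above 0. A genotype effect of the same size under injury restates the interaction: the median over 14 interferon genes, chosen after their values were seen, was 3.47 in sham and −0.96 in IR, where 13 of 14 were lower in cKO. These medians, and those of the leukocyte and single-copy genes, are on log2(FPKM + 0.1), unlike the interaction values. On log2(FPKM + 1) the sham median of the 14 genes was 2.69 to 3.24 with 1 sham library left out. A response of the kidney to loss of tubular Krt20 was not tested, and Krt20 was only 0.0650 FPKM in WT sham (5 reads in 3 libraries), so little of its RNA was present to be lost. It stays open, as do an infection or a difference in housing, litter or day of surgery, which are not given in the sources used here and would coincide with the group.

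WT IR 2 lay between the sham libraries and the other WT IR libraries, which bears on every comparison with WT IR. Placed on a scale from 0, the WT sham mean, to 1, the mean of the other WT IR libraries, its median was 0.525 for 629 genes higher in IR and 0.634 for 876 genes lower in IR. Sham RNA mixed into the library would place all genes at 1 share: cell cycle genes and proximal tubule genes differed by 0.189, but the same gap reached 0.320 in another WT IR library, so mixing and a milder injury in that kidney cannot be told apart here. Either may move the comparison of cKO IR with WT IR: without WT IR 2, the median of proximal tubule genes went from −0.38 to −0.13 and that of tubular injury markers from 0.54 to 0.36. Havcr1 was 485 FPKM in that library against 782 and 797 FPKM in the others.

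Krt20 was abundant in cKO IR, at 36.9 FPKM, and lower there than in WT IR, at 69.6 FPKM. Urothelium in the sample is argued against by the sum of 4 uroplakin genes, at most 0.514 FPKM in a cKO IR library. Milder injury in cKO IR would lower the other tubular injury markers, but the 20 others had a median log2 difference of 0.54, all above 0. That was known before the test was chosen. No marker was called in cKO IR against WT IR. The list with Krt20 did not pass by camera with an estimated correlation (adjusted p = 0.343) or by fry (0.0981). The values thus show no sign of milder injury, without establishing that injury was greater. Deletion in part of the Krt20-expressing tubular cells, expression in cells outside the deletion, and transcripts that lack the deleted part but still count toward the gene are candidate explanations that gene-level FPKM does not test.

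The other results that differed between the genotypes were as follows. Igha had an interaction of 3.01, Pdk4 4.13, Gm12208 −2.53, Pdp2 −1.12 and Ell 0.85. Igkc was at 3.29, a call lost without WT sham 2 (adjusted p = 0.0604), cKO sham 1 (0.0515) or cKO sham 2 (0.0563). Maff, at 1.44, lost its call without WT sham 2, cKO sham 2, cKO sham 3 or cKO IR 1 (0.0616 to 0.0748), and Nqo1, at 1.23, without these or WT sham 3 (0.0616 to 0.0806). Depp1, at 2.42, Cyp24a1, at 3.88, and Mcm5, at −1.16, were each kept in fewer than 5 of 12 runs with 1 library left out, with adjusted p up to 0.0900, 0.0844 and 0.111. By list, the medians were −0.89 for cell cycle genes and 0.43 for fatty acid oxidation genes, kept in all 12 runs, and adjusted p were 0.523 and 0.85 with an estimated correlation. They were −0.17 for proximal tubule, 0.22 for glycolysis and hypoxia, 0.28 for ferroptosis suppressors, 1.10 for immediate early and heat shock and −0.26 for collecting duct genes, each lost without at least 1 library, with adjusted p up to 0.747, 0.0708, 0.0668, 0.0625 and 0.102. With an estimated correlation these 5 had adjusted p of 0.892, 0.523, 0.523, 0.718 and 0.718, and fry passed no list.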

How the results depend on the processing

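Among the tests below, voom on the recovered reads and scaling to plain library totals were chosen only after the data had been seen. In cKO IR against WT IR, 0 genes were called as reported and under quantile normalization, no trend, the added 2-fold minimum, the replicate block and the fit on only the groups compared. Under median-ratio scaling, pseudocounts of 0.1 and 0.5, a minimum mean of 5 FPKM, robust variances, voom and plain library totals 1 gene was called, Pdp2, and 9 with no filter. The adjusted p of Pdp2 ranged from 0.00119 with array weights to 0.592 on only the groups compared. Array weights gave 1544 genes here, 8665 in WT IR against WT sham, 632 in cKO sham against WT sham and 1275 in the interaction. With them Krt20 passed at −1.22 in cKO IR against WT IR and −1.14 in the interaction (adjusted p = 0.00119 and 0.0024; over all alternatives 0.00119 to 0.592 and 0.0024 to 0.971). That fit stopped before it converged and gave WT IR 1 a weight of 12.9, against 0.224 to 2.06 for the others. With voom the interaction of Krt20 was 0.21 rather than −0.84, and with pseudocounts of 0.5 and 0.1 it was −0.78 and −0.46. Its sham libraries hold 0 to 4 reads, and whether that is the source was not tested. The added 2-fold minimum left 1084, 1639 and 89 genes in WT IR against WT sham, cKO IR against cKO sham and cKO sham against WT sham. The fit on only the groups compared gave 251 genes in cKO sham against WT sham.

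The labels number the replicates of every group alike, but do not say that a number marks a shared animal, litter or day. Deviations of same-numbered libraries correlated at −0.19 to 0.40 over 18 pairs, and 4 of 12 libraries correlated best with their own number. A replicate block gave 73 genes in the interaction, against 113, and moved no other count by over 1.5 times.

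With 1 library left out, 55 to 157 genes were called in cKO sham against WT sham, 41 to 150 in the interaction and 0 to 12 in cKO IR against WT IR. The median of proximal tubule genes in the interaction ranged from −0.40 to 0.14, that of oxidative phosphorylation genes in cKO IR against WT IR from −0.10 to 0.14, and that of neutrophil genes there from −0.42 to 0.56. Where the cause is not stated above, the cause was not tested. Of the counts and Krt20 values that answer the comparisons, 177 kept their side of the threshold or stayed within 1.5 times, 19 were stronger and 14 weaker. Named genes gave 15440 results on the same side, 238 newly past the threshold and 345 no longer past it, and lists gave 2260, 84 and 53, with 3 reversed. Under a minimum mean of 5 FPKM, cell cycle genes in cKO sham lost their call (median 0.22, adjusted p = 0.231). Depth limits what a value near 0 means: 3 reads of Krt20 correspond to 0.0916 to 0.117 FPKM. A test for raw counts, planned only for a table of counts, was not run on the recovered reads.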

Other observations

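The immunoglobulin list and the single genes named below were chosen after their values were seen; the tests of interferon class and of time of day were not. Further genes induced by interferons stood above their WT sham level in cKO sham. Isg15, a ubiquitin-like modifier, went from 9.15 ± 10.6 to 50.1 ± 14.1 FPKM and Ifit3 from 19.5 ± 22.2 to 146 ± 29.8 FPKM (SD, n = 3). Both were highest in WT sham 1 among the WT sham libraries (Isg15 21.4 against at most 3.05 FPKM, Ifit3 45.2 against 6.90 and 6.44 FPKM), and without it their log2 differences were 3.63 and 4.24 (adjusted p of 0.000992 and 0.00166). Gbp2, a guanylate-binding protein, went from 6.27 to 32.0 FPKM, and the antigen presentation genes Cd74 and H2-Ab1 from 116 to 241 and from 37.5 to 88.3 FPKM. Ifit3 and Gbp2 were called (adjusted p of 0.0419 and 0.0144), Ifit3 losing its call without any sham library other than WT sham 1 (0.102 to 0.181) and Gbp2 without any but WT sham 1 or cKO sham 1 (0.0608 to 0.0765), while Isg15, Cd74 and H2-Ab1 did not pass (0.0603, 0.146 and 0.0974). All 12 genes of an interferon gamma class and all 12 of a type I class were above 0. Medians over all 12 members of a class are on log2(FPKM + 0.1). A response led by interferon gamma and one led by type I interferon cannot be told apart, since the gamma class median minus the type I median was −0.48, with interquartile ranges of the fold that overlap (1.57 to 5.67 and 2.84 to 8.92), and the gamma list left out the called GTPases. The difference was −1.04 without WT sham 1, −0.06 without WT sham 2, −0.76 without cKO sham 2 and −0.31 without cKO sham 3. Over tested members alone, on log2(FPKM + 1), the order turned on WT sham 1. The gamma median was lower without it (1.92 against 2.04) and higher without any other sham library, as at 1.65 against 1.23 without WT sham 2. Of tested members 5 of 9 and 3 of 12 were called higher, a balance that turned on WT sham 1: without it 5 and 9 were, and without any other sham library 3 to 5 and 0.

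Immunoglobulin and plasma cell genes had a median log2 difference of −2.76 in cKO sham against WT sham on log2(FPKM + 0.1), over tested and untested members. Of 3 tested members 2, Igha and Igkc, were called lower. Jchain, which joins IgA and IgM units, went from 2.01 to 0.224 FPKM, and Mzb1 from 0.521 ± 0.235 to 1.17 ± 0.465 FPKM (SD, n = 3), both under the filter and not tested. The third tested member, Ighm, was at 3.65 and 3.38 FPKM (adjusted p = 0.935).

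Collection of the sham groups at another time of day stays open for the differences between cKO sham and WT sham. The median absolute log2 difference of 12 clock genes was 0.38, at percentile 100 of 10000 random lists of like expression, whose 95th percentile was 0.174. It was 0.25 without WT sham 2 and 0.57 without WT sham 3, and lay at percentile 99.8 or above whichever sham library was left out. The random lists were matched on expression, not on how far genes vary between libraries or vary together. Within WT sham the spread was wide for Dbp (20.9 ± 12.7 FPKM) and narrow for Nr1d1 (24.1 ± 1.65 FPKM). The percentile alone thus does not show a difference between the groups. Medians of a whole arm are on log2(FPKM + 0.1), and those over tested members or over the 12 clock genes on log2(FPKM + 1). Evening-arm genes had a median of 0.38, with 9 of 10 above 0 (0.26 without WT sham 1 and 0.62 without WT sham 3). Per2 went from 4.84 to 11.5 and Dbp from 20.9 to 37.5 FPKM. Morning-arm genes had a median of −0.70 over 5 members (−0.33 without WT sham 2, −0.45 without cKO sham 1 and −1.12 without cKO sham 2), with Arntl going from 1.31 to 0.267 FPKM. Over the 3 tested members it was −0.004, with a sign that changed without WT sham 1, cKO sham 1 or cKO sham 2, so the arms were not shown to move apart. Cry1, of the morning arm, was higher and the 1 clock gene called, a call lost without any sham library other than cKO sham 3 (adjusted p of 0.0994 to 0.175). In cKO IR against WT IR the clock genes were also at percentile 100, with the morning arm at 0.53, the evening arm at −0.63 and 0 called in limma. The labels give no time of collection, so another time of day, a genotype effect on the clock and spread between libraries cannot be told apart.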
